A study of Homo sapiens with 9 samples.

How the data were processed

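RNA was measured by mRNA sequencing in A375 cells, an established human melanoma line that carries an activating BRAF mutation. The cells were left untreated or were given Salvianolic acid B (SalB), a water-soluble phenolic compound of the herb Salvia miltiorrhiza, at 100 µM or 200 µM for 48 h. Each of the 3 groups held 3 libraries, which the labels describe as biological replicates, and the labels give 1 batch value for all 9 libraries. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was captured on poly-T beads, libraries were made with a NEBNext Ultra RNA kit, and sequencing was paired-end on an Illumina instrument. The capture on poly-T beads limits the data to polyadenylated transcripts.

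The main file held whole-number read counts per gene and library, deposited by the authors without normalization. Per the submitters' processing notes, FastQC, HISAT2, featureCounts and DESeq2 were used with GRCh38, with no versions or roles stated; the annotation release and the strand setting of the counting are not given in the sources used here. Because the strand setting is unknown, a gene and an antisense or overlapping partner can share reads. Overlaps of at least 10% of a gene's exons, a bound chosen after the data were seen, are marked beside the values. Smaller overlaps, of 9% or less, are not marked there, and their genes are open to the same doubt: THBS1, VCAN, IGFBP5, CCN2, IFIT2, RPL31, DNAJB1, NPC1, CDKN1A, CRELD2, ESM1, H4C14, KIF2C, LIF, LPIN1, MYH14, NDUFB6, PDE3A, RSAD2, TIPARP, TNC, VEGFA, BCL3 and SLC16A6. A further table held expression values for 100 features in the same 9 libraries, deposited by the authors and read here as FPKM. That unit was inferred from the values: the ratio of transcript length implied by counts and values to the annotated length had a median of 1.03 (quartiles 0.924 and 1.08) over 98 features. How the authors chose the 100 features is not given in the sources used here.

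The count table had 22605 features, of which 20463 were annotated genes with Ensembl identifiers and 2142 were transcripts assembled by the authors that carry no Ensembl identifier. The assembled transcripts took 1.25% to 1.41% of the counts of a library and were left out of the tests of genes, a choice made after the files were examined. For 1012 annotated genes the table gave no symbol, and 1000 of these were matched to a symbol by identifier. Gene positions, transcript lengths, GC content and exon overlaps came from the GENCODE v29 annotation on GRCh38, and GC content was known for 99.3% of the genes tested.

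Depth was similar across libraries, at 27348621 to 30629685 counts, and between 15121 and 15565 genes had at least 1 count. Intervals for shares of counts in single libraries are Wilson 95% intervals and cover counting error only. All pairs of libraries within a group differed beyond sampling noise, with chi-square per degree of freedom between 7.47 and 155, so no library was counted as a copy of another.

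Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 13968 genes, library sizes were scaled by TMM, and a robust quasi-likelihood model was fitted to all 9 libraries with the group as its term, which leaves 6 residual degrees of freedom. The quasi-likelihood F test compared 100 µM with control, 200 µM with control and 200 µM with 100 µM, and p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons. A gene was called at an adjusted p under 0.05, with no minimum fold. Log2 fold changes are given with standard errors, each taken as the size of the log2 fold change divided by the square root of its F value. These errors rest on the spread shared by all groups. Expression is given as CPM, computed here from the authors' counts with TMM-scaled library sizes, as mean ± SD of 3 libraries. An exact permutation test of a single value between groups of 3 libraries cannot give a two-sided p below 0.1, so p-values are taken from the model alone.

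The 31 gene lists were written before the data were examined and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists in each comparison. They cover the cell cycle, p53 and apoptosis, melanocyte and dedifferentiated melanoma genes, adhesion, stress and metabolic programs, interferon, NF-kB, MAPK, YAP and AHR targets, protein synthesis, mitochondria, histones, and markers of leukocytes, epithelium, and fibroblasts or endothelium. Counts of list members are given from the test over all genes and, where different, adjusted over the list alone. Some genes stand in several lists, so the calls of different lists are not independent of each other.

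The groups, tests, gene lists, named genes and a first set of alternatives were fixed before the data were examined. The text names, for each comparison against control, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among genes with a mean of at least 5 CPM and no overlap between the groups' libraries. For 200 µM against 100 µM it names 4 in each direction. It also names the 2 called members with the smallest p of each called list, and the 9 landmark genes CDKN1A, MKI67, CCND1, MYC, BAX, BCL2, MITF, HMOX1 and DDIT3 whatever their test. Of the genes selected by this rule, 1 is not reported here. Any other gene was chosen after its values were seen.

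The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, scaling by RLE or by total count alone, no filter or a filter at 1 CPM in 3 libraries, fits of the 2 groups compared, the replicate number as a block, a minimum log2 fold change of 1, an adjusted p under 0.01, library sizes without the 20 most abundant genes, camera with estimated correlations, fry, and fits without each library in turn. Corrections that removed each library's trend of log2 CPM against GC content (lowess span 0.3), alone or with transcript length, and the fit with the assembled transcripts kept were added after the data were seen. The overlap between doses without 200 µM replicate 3 was added then too. Gene families defined by shared symbol stems with at least 10 measured members were also chosen after the data were seen. The relation between the doses was set beside 20 simulations in which control and unchanged groups were drawn from the same means. That design was set after the results were seen, since an earlier one kept the observed controls and so left out the error they share.

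The steps were tested on simulated data drawn from the real means and library sizes. For 100 µM against control, over 13832 genes, 2% of 50 genes changed by 0.5 on the log2 scale were recovered, 68% at 1, 78% at 2 and 98% at 3, and 5 of the 128 genes called were unchanged ones. For 200 µM against control, over 13825 genes, recovery was 24%, 64%, 94% and 92% at the same sizes, and 8 of the 145 genes called were unchanged ones. Each was a single run from the same means and spread with different genes drawn. Their gap therefore does not show a difference in sensitivity between the doses. The bar that recovery had to pass at a log2 change of 2 or more was lowered from over 90% to over 70% after the 100 µM value was seen. In a simulated GC trend between 100 µM and control with no group effect, over 13968 genes, the Spearman correlation of fold change with GC content was 0.759 before the GC correction and 0.0187 after it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.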

Results

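Gene expression was measured by mRNA sequencing in 9 libraries of A375 cells, an established human melanoma line. The cells were untreated or had been exposed for 48 h to Salvianolic acid B (SalB), a phenolic compound from the root of Salvia miltiorrhiza, at 100 µM or 200 µM, with 3 libraries in each group. The series therefore has 3 comparisons: each dose against the untreated control, and the higher dose against the lower. Total counts were 29658753 to 30063195 in the control libraries, 29996059 to 30629685 at 100 µM and 27348621 to 28468350 at 200 µM. The quasi-likelihood test of edgeR was applied to 13968 genes, and values are given as mean ± SD over n = 3 libraries or as log2 fold change ± SE. Where the count of a list's members adjusted over the list alone differed from that over all genes, it is given beside the list's counts of higher and lower members.

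The libraries separated by treatment. The first principal component held 42.4% of the variance and placed control between the 2 doses, and the second held 23.7% and parted control from both doses. The third, with 11.8%, set 200 µM replicate 3 apart from the other libraries of its group. The 13 mitochondrially encoded mRNAs took 2.20% ± 0.108 of counts in control and 2.98% ± 0.152 at 100 µM. In the 200 µM group their share was 1.87% in replicate 1 (Wilson 95% interval 1.87 to 1.88), 1.83% in replicate 2 (1.83 to 1.84) and 4.75% in replicate 3 (4.74 to 4.76). Libraries also differed in the level of GC-rich transcripts. The log2 gap between the GC-richest and GC-poorest eighth of genes, relative to the control mean, lay between -0.16 and 0.16 in control, between 0.69 and 0.93 at 100 µM, and at 0.48, 0.96 and -0.31 in the 3 libraries at 200 µM.

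**Figure D1:**
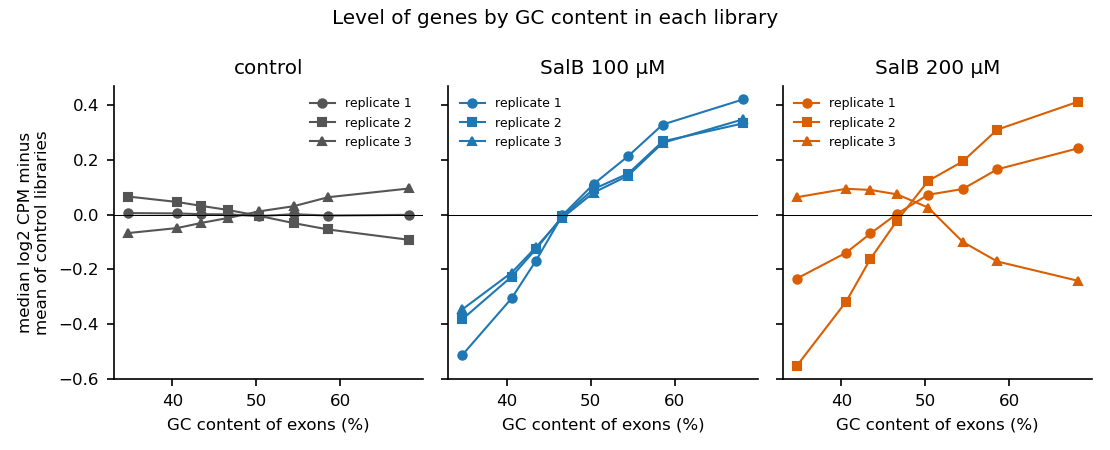
Median log2 CPM minus the control mean (y axis) for genes in 8 equal parts of GC content (x axis, percent), with 1 line for each of the 9 libraries, coloured by group. The lines of the 100 µM libraries climb toward GC-rich genes, and 200 µM replicate 3 slopes the other way from the other 200 µM libraries, with a gap of -0.31 between the outer parts.

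The comparison of 100 µM with control addressed which transcripts the lower dose changed. Transcripts of inflammatory mediators fell together. Of 30 measured members of the NF-kB and inflammatory cytokine list, 27 were lower and 1 was higher (median log2 fold change -2.96; camera adjusted p = 1.1e-67). *CXCL8*, which encodes the neutrophil attractant interleukin-8, went from 1344 ± 185 CPM to 29.6 ± 5.39 CPM, 45.4-fold lower. *IL1B*, encoding interleukin-1 beta, was 64.1-fold lower. Hypoxia and HIF targets fell as well (23 of 34 members lower), with *BNIP3*, a mitophagy receptor, 4.09-fold lower. Extracellular matrix genes rose (23 of 39 members higher), with *THBS1*, encoding the matrix protein thrombospondin 1, 6.52-fold higher.

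*CXCL8* (ENSG00000169429, protein-coding, GRCh38 chromosome 4, 73740506 to 73743716) had a log2 fold change of -5.51 ± 0.23 (adjusted p = 1.3e-06). *IL1B* (ENSG00000125538, protein-coding, chromosome 2, 112829751 to 112836903) fell from 33.4 ± 0.722 to 0.518 ± 0.367 CPM, a log2 fold change of -6.00 ± 0.36 (adjusted p = 8.5e-06). *IL24* (ENSG00000162892, protein-coding, chromosome 1, 206897443 to 206904139), a cytokine of the interleukin-10 family, fell from 118 ± 3.32 to 6.77 ± 0.220 CPM, 17.4-fold lower. *BIRC3* (ENSG00000023445, protein-coding, chromosome 11, 102317450 to 102339403), an inhibitor of apoptosis, changed by -5.49 ± 0.21 on the log2 scale, and *TRAF1*, an adaptor of TNF receptors, by -3.46 ± 0.12. Other strong decreases were those of *TNFRSF9* (-5.25 ± 0.42), a TNF receptor family member, complement *C3* (-4.84 ± 0.22), *ESM1* (-4.72 ± 0.12), a secreted proteoglycan, and *IL1A* (-4.17 ± 0.28), encoding interleukin-1 alpha. *SERPINB2* also fell by 6.53 ± 0.51 on the log2 scale, but shares 20% of its exons with *SERPINB10* and is uncertain. The largest adjusted p among these 8 strongest decreases was 3.8e-05. *BCL3*, chosen after its values were seen, is the member of the NF-kB list that rose (1.22 ± 0.14), and it encodes a nuclear IkB family protein.

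The hypoxia and HIF target list had 23 of 34 measured members lower and 2 higher (24 lower and 3 higher adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 1.8e-11). *BNIP3* (ENSG00000176171, protein-coding, chromosome 10, 131966455 to 131982013) fell by 2.03 ± 0.09 on the log2 scale and *NDRG1*, a stress-responsive differentiation gene, by 1.59 ± 0.09. The extracellular matrix and adhesion list had 23 of 39 members higher and 6 lower (23 and 8 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 5.6e-09). *THBS1* (ENSG00000137801, protein-coding, chromosome 15, 39581079 to 39599466) rose from 54.4 ± 0.420 to 354 ± 7.11 CPM (adjusted p = 3.7e-08). *COL5A2* (ENSG00000204262, protein-coding, chromosome 2, 189031896 to 189225312), a chain of fibrillar collagen V, was 3.49-fold higher. The strongest increases also held the matrix proteoglycan *VCAN* (2.90 ± 0.18), the secreted matrix protein gene *OLFML2A* (2.92 ± 0.17), *SEMA6B* (2.46 ± 0.20), a semaphorin, *ATOH8* (2.45 ± 0.11), a transcription factor, *MYH14* (2.40 ± 0.18), a nonmuscle myosin, and *IGFBP5* (2.27 ± 0.15), an insulin-like growth factor binding protein. *GASK1B* rose by 2.79 ± 0.23 but overlaps an antisense gene over 13% of its exons and is uncertain.

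The NF-kB, hypoxia and matrix lists were the 3 of 12 called lists that also passed with an estimated correlation, with adjusted p-values of 5.1e-05, 0.0096 and 0.0096. Each of the other 9 was lost in that test, as given beside it. Cytosolic ribosomal protein genes had 37 of 75 members lower and 0 higher (41 lower adjusted over the list alone), a median of -0.35 and a camera adjusted p of 1.7e-05 (adjusted p = 0.25 with an estimated correlation). In the fit without 200 µM replicate 3, which enters the shared estimate of the spread, 56 were lower and 2 higher. Ribosomal protein genes have near-identical copies in the genome, so single members such as *RPL31* (-0.56 ± 0.08) and *RPS3A* (-0.55 ± 0.07, with 11% of its exons shared with *SH3D19*) are uncertain, and the call of *RPS3A* ended after GC correction (-0.27, adjusted p = 0.088) and after the GC and length correction (-0.02, 0.89). Apoptosis regulators had 17 of 36 members lower and 1 higher (19 and 1 adjusted over the list alone, 20 and 5 without 200 µM replicate 3), with a median of -0.43 and a camera adjusted p of 2.8e-05 (adjusted p = 0.14 with an estimated correlation). The 2 members with the smallest p, *BIRC3* and *BCL2A1* (-3.79 ± 0.25), both restrain cell death. NRF2 targets, the antioxidant program, had 16 of 33 members lower and 2 higher (16 and 4 adjusted over the list alone, 20 and 4 without 200 µM replicate 3), with a median of -0.33 and a camera adjusted p of 0.0018 (adjusted p = 0.15 with an estimated correlation). Among them *TXNRD1*, a thioredoxin reductase, changed by -0.68 ± 0.08, and *SQSTM1*, an autophagy adaptor, by -1.46 ± 0.15, with 21% of its exons shared with *MRNIP*.

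MAPK pathway output genes had 12 of 28 members lower and 6 higher, a median of -0.27 and a camera adjusted p of 0.013 (adjusted p = 0.13 with an estimated correlation). *LIF*, a cytokine of the interleukin-6 family, changed by -1.85 ± 0.14, and *CCND1*, encoding cyclin D1, by -1.05 ± 0.10, with 10% of its exons shared with *LTO1*. Cholesterol synthesis genes had 11 of 25 members lower and 1 higher (12 and 2 adjusted over the list alone, 13 and 5 without 200 µM replicate 3), a median of -0.25 and a camera adjusted p of 0.017 (adjusted p = 0.15 with an estimated correlation). These included *INSIG1* (-0.79 ± 0.10), a sterol-regulated membrane protein. AHR targets had 4 of 11 members lower and 3 higher, with a median of -0.33, a mean of -1.17 and a camera adjusted p of 0.018 (adjusted p = 0.13 with an estimated correlation, and 0.051 with the preset correlation without control replicate 3). The AHR median was -0.20 without 200 µM replicate 3, -0.21 without 200 µM replicate 1, -0.20 without control replicate 2, -0.24 without control replicate 3, and -0.22 and -0.18 without 100 µM replicates 1 and 2. The members with the largest falls in the AHR list were *SERPINB2* and *IL1B*, whereas *CYP1A1*, a classical AHR target chosen after its values were seen, rose by 1.86 ± 0.25. YAP and TGF-beta targets had 16 of 28 members higher and 6 lower, a median of 0.55 and a camera adjusted p of 0.018 (adjusted p = 0.13 with an estimated correlation). *CCN2*, a matricellular YAP target, rose by 1.83 ± 0.09. Against the direction of its list, *IGFBP3* (ENSG00000146674), which binds insulin-like growth factors, was 9.35-fold lower, at 148 ± 2.39 against 1381 ± 9.38 CPM.

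The dedifferentiated and invasive melanoma list had 19 of 39 members higher and 9 lower, including *THBS1* upward and *CXCL8* downward. Its median was 0.20 and its mean -0.03, while the test gave higher expression (camera adjusted p = 0.0060; adjusted p = 0.13 with an estimated correlation), and the median was 0.33 without control replicate 3 and 0.30 without 100 µM replicate 2. Metal response genes had 6 of 12 members lower and 0 higher, a median of -0.26 and a camera adjusted p of 0.041 (adjusted p = 0.14 with an estimated correlation). They included the iron uptake receptor *TFRC* (-1.08 ± 0.11) and *FTH1* (-0.93 ± 0.12), encoding ferritin heavy chain, which shares 62% of its exons with *BEST1* on the other strand and is uncertain. Without 100 µM replicate 2 or replicate 3 the metal response list had adjusted p-values of 0.060 and 0.051, and with the filter of 1 CPM in 3 libraries 0.052. Fold changes at 100 µM rose with GC content across genes (Spearman 0.48 over 13874 genes, which are not independent replicates). Removal of each library's GC trend ended the calls of the dedifferentiated list (median 0.07, adjusted p = 0.076), the YAP list (0.36, 0.11) and the metal response list (-0.12, 0.12). With length corrected too, the values were 0.12 (adjusted p = 0.059), 0.46 (0.059) and -0.12 (0.16). Without 200 µM replicate 3, which enters the shared estimate of the spread, the YAP list had a median of 0.58 and an adjusted p of 0.11.

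Cell-cycle lists were not called at 100 µM: the G2/M list had 6 of 40 members higher and 5 lower (median -0.10), and the DNA replication list 9 of 44 higher and 6 lower (median -0.02). Without 200 µM replicate 3 the G2/M list had 9 higher and 16 lower (median -0.08) and the DNA replication list 17 and 11 (median 0.01), and after GC correction they had 12 and 5, and 9 and 7. Without control replicate 1 the DNA replication median was -0.07. The landmark genes moved in both directions. *MKI67*, a proliferation marker, rose by 0.89 ± 0.23 (edgeR adjusted p = 0.015), a call lost without control replicate 1 (0.053), control replicate 2 (0.052) or 100 µM replicate 1 (0.053), and after the GC and length correction (0.63, 0.053). *CDKN1A*, encoding the cell-cycle inhibitor p21, fell by 0.69 ± 0.15, and *MITF*, the melanocyte lineage regulator, fell by 0.70 ± 0.15. *DDIT3*, encoding the stress factor CHOP, fell by 0.97 ± 0.12 and overlaps *MARS* over 27% of its exons. *MYC* (0.24 ± 0.10), *BAX* (0.41 ± 0.20), *BCL2* (0.14 ± 0.16) and *HMOX1* (-0.26 ± 0.17), which encodes heme oxygenase 1, were not called, with adjusted p from 0.089 to 0.53. *MYC* was called without 200 µM replicate 2 (0.042) or replicate 3 (0.021), with total-count scaling (0.034) and in the fit of the 2 groups alone (0.019). *BAX* was called without 200 µM replicate 3 (2.5e-04), in the fit of the 2 groups alone (4.2e-05) and after the GC and length correction (0.017), and *HMOX1* after GC correction (0.0067). Of the other lists, the interferon-stimulated genes had 4 of 40 members higher and 11 lower (6 and 12 adjusted over the list alone; camera adjusted p = 0.075, and 0.040 without control replicate 2), and 7 higher and 12 lower without 200 µM replicate 3. Fatty acid synthesis genes had 6 of 16 members higher and 2 lower (camera adjusted p = 0.056). That list was called without control replicate 2 (0.041), 100 µM replicate 1 (0.045), 200 µM replicate 2 (0.023) or 200 µM replicate 3 (0.036), and after GC correction (0.0044), after the GC and length correction (0.026) and with the assembled transcripts kept (0.033), and had 7 higher and 4 lower without 200 µM replicate 3.

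Glycolysis had 4 of 22 members higher and 8 lower (camera adjusted p = 0.13), and was called as lower after GC correction (7.5e-04), after the GC and length correction (0.0012) or without 200 µM replicate 3 (0.043). Of the 13 mitochondrially encoded mRNAs, 1 was higher (median 0.42, camera adjusted p = 0.35), and without 200 µM replicate 3 the list was called as higher (0.0010), with 9 members higher. It was also called after the GC and length correction (median 0.94, adjusted p = 0.026). The further lists were not called at 100 µM. They were p53 targets (5 higher and 8 lower of 32, or 5 and 9 adjusted over the list alone), melanocyte genes (4 and 6 of 24), the unfolded protein response (7 and 7 of 29), the ATF4 response (8 and 8 of 35), heat shock genes (7 and 3 of 25), ferroptosis regulators (5 and 9 of 25), nuclear OXPHOS subunits (4 and 14 of 49), ribosome biogenesis (10 and 4 of 40) and histones (0 and 1 of 19, or 0 and 0 adjusted over the list alone). The higher and lower members without 200 µM replicate 3 were 9 and 11 for p53 targets, 11 and 9 for the unfolded protein response, 14 and 9 for the ATF4 response, 12 and 5 for heat shock genes, 13 and 20 for OXPHOS subunits and 14 and 11 for ribosome biogenesis. Autophagy and lysosome genes had 13 of 43 members higher and 10 lower, with a median of -0.07, a mean of 0.04 and a test in the upward direction, and the median was -0.05 without 200 µM replicate 2 or 3, -0.04 without control replicate 3 and -0.02 without 100 µM replicate 3. Markers of other cell types were not called: fibroblast and endothelial genes had 6 of 10 higher and 2 lower (6 and 3 adjusted over the list alone; median 0.76, camera adjusted p = 0.22), epithelial genes 2 and 2 of 9, and leukocyte genes 0 and 0 of 7.

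In all, 5181 genes differed between 100 µM and control at an adjusted p under 0.05, 2640 higher and 2541 lower, of which 1103 had a log2 fold change of at least 1 in size. Without 200 µM replicate 3 the fit called 7943 genes, 4056 higher and 3887 lower, and a fit of the 2 groups alone called 8417, 4098 higher and 4319 lower. The number of lower genes was 1689 without control replicate 1, 1632 without control replicate 2, 1613 without 100 µM replicate 1 and 1619 without 100 µM replicate 2.

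**Figure D2:**
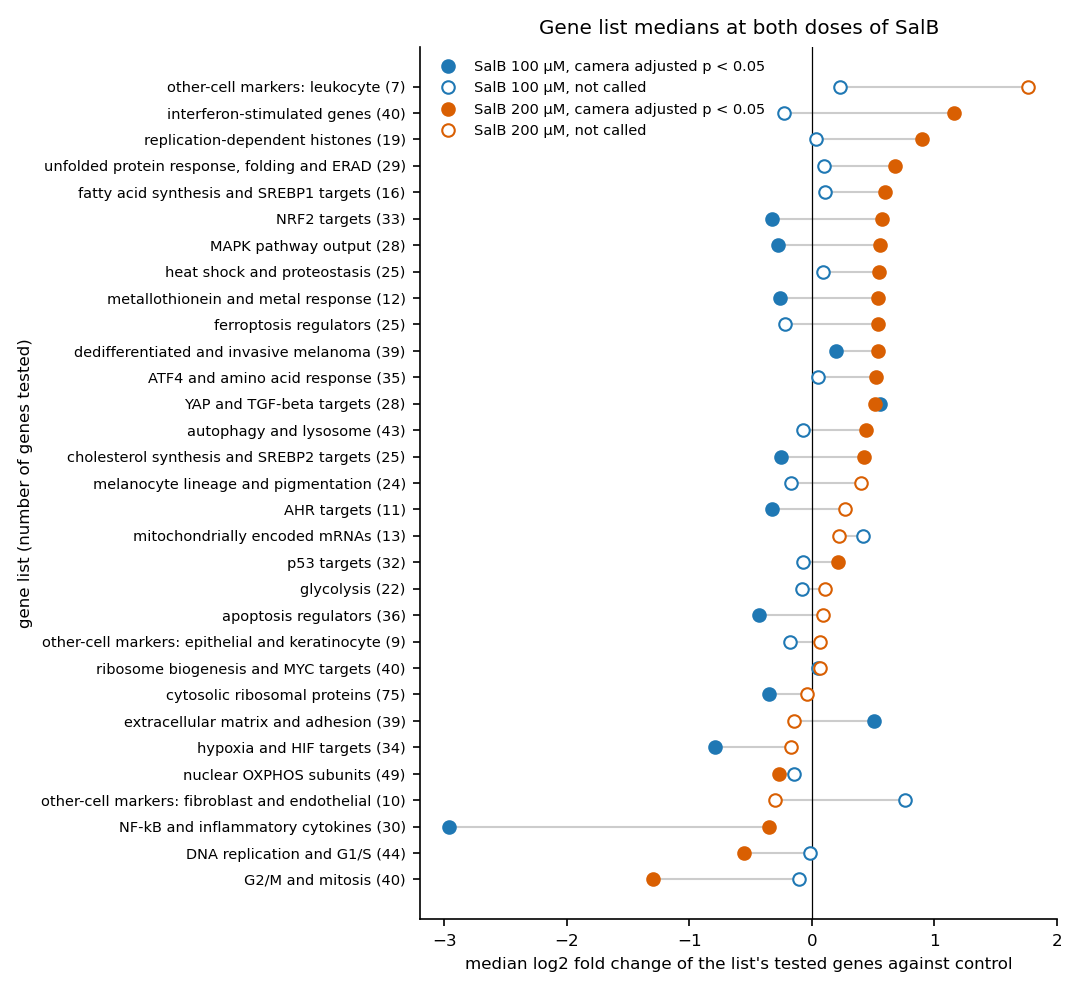
Median log2 fold change against control (x axis) of each of the 31 gene lists (y axis) at 100 µM and 200 µM, with filled points for lists with a camera adjusted p under 0.05. The NF-kB list has medians of -2.96 and -0.35 at the 2 doses, and the G2/M list -0.10 and -1.29.

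The comparison of 200 µM with control addressed which transcripts the higher dose changed. Mitotic genes fell together, with 38 of 40 members of the G2/M list lower and 0 higher (median log2 fold change -1.29; camera adjusted p = 6.5e-37). *CCNB1*, encoding the mitotic cyclin B1, went from 373 ± 6.84 to 115 ± 4.23 CPM, 3.24-fold lower. Interferon-stimulated genes rose, with 24 of 40 members higher and 0 lower (26 and 0 adjusted over the list alone; median 1.16; camera adjusted p = 3.1e-21). Their strongest member was *OASL*, encoding an oligoadenylate synthetase-like protein, which went from 0.367 ± 0.114 to 61.7 ± 12.5 CPM, 167-fold higher. NRF2 targets, the antioxidant program, rose too (21 of 33 members higher), and *HMOX1*, encoding heme oxygenase 1, was 30.5-fold higher at 229 ± 46.6 against 7.50 ± 0.514 CPM.

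*HMOX1* (ENSG00000100292, protein-coding, GRCh38 chromosome 22, 35380361 to 35394214) had a log2 fold change of 4.93 ± 0.19 (adjusted p = 7.6e-07). *OASL* (ENSG00000135114, protein-coding, chromosome 12, 121019111 to 121039242) changed by 7.38 ± 0.27 (adjusted p = 5.8e-07). *CCL5*, a chemokine that attracts T cells, had 8 counts over the control libraries and 1214 at 200 µM (7.31 ± 0.44). *RSAD2*, encoding the antiviral protein viperin, rose by 5.54 ± 0.36, *ARC*, an immediate early gene, by 3.93 ± 0.23, and *KLF2*, a transcription factor, by 3.78 ± 0.10. *IFIT2* (ENSG00000119922, protein-coding, chromosome 10, 89283694 to 89309276), an antiviral protein gene, was 12.2-fold higher. *SYNC* rose by 3.79 ± 0.17 but shares 49% of its exons with *RBBP4*, and *BEST1* (6.49 ± 1.28) shares 14% of its exons with *FTH1* and ranged from 61.9 to 527 CPM over the 3 libraries, so both are uncertain. Inflammatory genes were among the decreases, with *IL1B* 68.6-fold lower and *CXCL8* 27.4-fold lower, at 49.1 ± 11.3 CPM. *CXCL1* (-3.84 ± 0.16) and *CCL2* (-3.81 ± 0.22), chemokines for neutrophils and monocytes, fell too, as did *TNFRSF9* (-3.87 ± 0.38), *IL1A* (-3.41 ± 0.27) and the phosphodiesterase gene *PDE3A* (-3.41 ± 0.16). *PSMB3*, a proteasome subunit, was lower by -7.34 ± 0.92 on the log2 scale, but varied from 32.6 to 70.1 CPM among the control libraries and is uncertain.

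The NF-kB list as a whole was lower, with 16 of 30 members lower and 7 higher (median -0.35; camera adjusted p = 4.8e-06). Among the members that rose was *IL24*, 11.2-fold higher than in control at 1324 ± 270 CPM. DNA replication genes had 33 of 44 members lower and 2 higher (34 and 2 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 2.7e-09). *RRM2*, a ribonucleotide reductase subunit that shares 20% of its exons with another annotated gene, fell by 1.05 ± 0.07. The members that rose were *CCNE1*, encoding cyclin E1 of the G1/S transition (1.04 ± 0.09), and *CDC25A* (0.54 ± 0.12), a phosphatase that activates cyclin-dependent kinases, the latter named after its values were seen. *UBE2C*, a mitotic ubiquitin-conjugating enzyme, fell by 1.40 ± 0.07, and *CCNB1* (ENSG00000134057, protein-coding, chromosome 5, 69167010 to 69178245) had a log2 fold change of -1.70 ± 0.07 (adjusted p = 1.1e-06).

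Stress lists rose at 200 µM. They share members, so they are not separate pieces of evidence: *HMOX1* and *FTH1* stand in the NRF2, metal response and ferroptosis lists. NRF2 targets had 21 of 33 members higher and 1 lower (23 and 2 adjusted over the list alone; median 0.58; camera adjusted p = 4.3e-13), among them *ABCC2*, an organic anion exporter (1.58 ± 0.07). The unfolded protein response list had 18 of 29 members higher and 0 lower (median 0.68; camera adjusted p = 3.0e-10), with the chaperone *HSPA5* at 1.36 ± 0.07 and *CRELD2*, an endoplasmic reticulum stress gene, at 2.05 ± 0.12. The ATF4 and amino acid response list had 23 of 35 members higher and 2 lower (23 and 3 adjusted over the list alone; median 0.52; camera adjusted p = 1.0e-07), and was lost with an estimated correlation (adjusted p = 0.056 with an estimated correlation). *ATF3* rose by 2.99 ± 0.16 and *DDIT3*, with its overlap, by 1.77 ± 0.12. Heat shock and proteostasis genes had 13 of 25 members higher and 1 lower (15 and 1 adjusted over the list alone; median 0.55; camera adjusted p = 3.3e-06), including the co-chaperone *DNAJB1* (1.16 ± 0.09) and *HSPA1A* (2.93 ± 0.16), which has the near-identical copy *HSPA1B* and is uncertain. Metal response genes had 6 of 12 members higher and 1 lower (median 0.54; camera adjusted p = 6.6e-06), with *FTH1* at 1.87 ± 0.13, and 6 higher and 3 lower without 200 µM replicate 3 (median 0.36). The heat shock list then had 15 higher and 4 lower. Ferroptosis regulators had 15 of 25 members higher and 2 lower (median 0.54; camera adjusted p = 2.3e-06). The members with the smallest p were *HMOX1*, whose product releases iron from heme, and *SCD* (1.05 ± 0.06), a fatty acid desaturase that is known to protect cells from ferroptosis. Autophagy and lysosome genes had 27 of 43 members higher and 3 lower (29 and 3 adjusted over the list alone; median 0.44; camera adjusted p = 3.4e-07; adjusted p = 0.078 with an estimated correlation). *SQSTM1* rose by 1.94 ± 0.15 and *NPC1*, a lysosomal cholesterol transporter, by 1.24 ± 0.10.

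Lipid synthesis lists were higher. Cholesterol synthesis genes had 14 of 25 members higher and 0 lower (median 0.43; camera adjusted p = 4.8e-06), with *INSIG1* 2.98-fold higher and *HMGCS1*, an early enzyme of the pathway with 15% antisense overlap, at 1.65 ± 0.09. Fatty acid synthesis genes had 11 of 16 members higher and 0 lower (12 and 0 adjusted over the list alone; median 0.60; camera adjusted p = 8.6e-05), with *LPIN1*, a phosphatidate phosphatase, at 0.84 ± 0.08. MAPK pathway output had 19 of 28 members higher and 0 lower (21 and 1 adjusted over the list alone; median 0.56; camera adjusted p = 3.3e-07). Its leading members were *DUSP5* (2.62 ± 0.16), a phosphatase that restrains ERK, and *FOSL1* (2.12 ± 0.16), an AP-1 subunit. YAP and TGF-beta targets had 17 of 28 members higher and 6 lower (19 and 6 adjusted over the list alone; median 0.52; camera adjusted p = 9.6e-06), with the matricellular gene *CCN1* at 2.72 ± 0.09 and *IGFBP3* lower at -1.96 ± 0.07. The dedifferentiated melanoma list had 23 of 39 members higher and 6 lower (23 and 7 adjusted over the list alone; median 0.54; camera adjusted p = 3.7e-09), and *THBS1* was 6.39-fold higher at 347 ± 3.84 CPM.

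The remaining lists called at 200 µM were p53 targets, nuclear OXPHOS subunits and histones. The p53 targets had 12 of 32 members higher and 3 lower (13 and 3 adjusted over the list alone), a median of 0.21 and a camera adjusted p of 0.023 (adjusted p = 0.23 with an estimated correlation, and 0.060 with the preset correlation without 200 µM replicate 1). *GDF15*, a stress cytokine, rose by 2.81 ± 0.24, *GADD45A* by 1.01 ± 0.10 and *CDKN1A* by 1.08 ± 0.15. Nuclear OXPHOS subunits had 18 of 49 members lower and 0 higher, a median of -0.27 and a camera adjusted p of 4.0e-04 (adjusted p = 0.12 with an estimated correlation). Complex I subunits *NDUFB6* and *NDUFV2* fell by 0.61 ± 0.07 and 0.61 ± 0.06, the latter with 28% exon overlap. Replication-dependent histone genes had 9 of 19 members higher and 1 lower (10 and 1 adjusted over the list alone), a median of 0.90 and a camera adjusted p of 0.047 (adjusted p = 0.10 with an estimated correlation). That call was also lost after GC correction (median 0.82, adjusted p = 0.15), without control replicate 3 (0.84, 0.059), without 200 µM replicate 2 (0.64, 0.056), without 200 µM replicate 3 (0.85, 0.21) and with the assembled transcripts kept (0.90, 0.068). Histone transcripts are mostly not polyadenylated and have near copies, so the values of *H2AC6* (0.90 ± 0.12) and *H4C14* (1.11 ± 0.16) are uncertain. Of the 19 called lists, 14 held with an estimated correlation, all but the ATF4, autophagy, OXPHOS, p53 and histone lists.

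Among the landmark genes at 200 µM, *MYC* rose by 0.91 ± 0.10 and *MITF* fell by 0.52 ± 0.15 (edgeR adjusted p = 0.026). The *MITF* call was lost without control replicate 1 (-0.55, 0.057), control replicate 2 (-0.44, 0.098) or control replicate 3 (-0.56, 0.050). It was also lost without 200 µM replicate 1 (-0.55, 0.051) and in the fit of the 2 groups alone (-0.52, 0.064). *MKI67* was not called (-0.34 ± 0.23, adjusted p = 0.28). Its values were 139, 147 and 281 CPM in the 3 libraries, and without 200 µM replicate 3 it was called as lower (-0.72, 3.4e-06). *BAX* (0.10 ± 0.20), *BCL2* (0.28 ± 0.16) and *CCND1* (0.27 ± 0.10) were not called, with adjusted p from 0.055 to 0.73. *BAX* was called without 200 µM replicate 3 (0.36, 0.0019), *BCL2* without 200 µM replicate 2 (0.43, 0.031), and *CCND1* without 200 µM replicate 2 (0.039) or replicate 3 (0.0061), with DESeq2 (0.032), with RLE scaling (0.048), without the 20 most abundant genes in the library size (0.049) and after GC correction (0.044).

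The matrix list was not called at 200 µM, with 12 of 39 members higher and 14 lower (13 and 15 adjusted over the list alone), a median of -0.14, a mean of -0.10 and a test in the upward direction, and the median was -0.05 without 200 µM replicate 3, -0.04 without control replicate 1 and -0.08 without 100 µM replicate 1 or 2. Hypoxia targets had 11 of 34 higher and 12 lower (11 and 13 adjusted over the list alone), melanocyte genes 8 and 3 of 24 (10 and 3), apoptosis regulators 7 and 7 of 36, glycolysis 7 and 6 of 22, cytosolic ribosomal proteins 2 and 6 of 75 (0 and 0), and ribosome biogenesis 6 and 6 of 40 (6 and 5), none of them called. In the fit without 200 µM replicate 3 the apoptosis list had 14 higher and 7 lower, ribosomal proteins 10 and 12, and ribosome biogenesis 10 and 10. AHR targets had 4 of 11 higher and 1 lower, with a median of 0.27 and a mean of -0.05, and were not called, with a median of 0.41 without control replicate 2, 0.49 without 200 µM replicate 1 and 0.45 without 200 µM replicate 3. Of the 13 mitochondrially encoded mRNAs none was called (median 0.22, camera adjusted p = 0.80), but without 200 µM replicate 3, the library with 4.75% of counts from them, the list was called as lower (median -0.51, 0.011; 1 higher and 7 lower), and the median was 0.44 without control replicate 1 and 0.48 without 200 µM replicate 1 or 2. Markers of other cell types were not called: leukocyte genes had 3 of 7 higher and 1 lower (median 1.77, camera adjusted p = 0.083), epithelial genes 3 and 1 of 9, and fibroblast and endothelial genes 4 and 2 of 10 (4 and 3 adjusted over the list alone; median -0.30, mean 0.09, test upward), and the last median was -0.19 without control replicate 2 and 0.00 without 200 µM replicate 1. With the replicate number as a block, the leukocyte list was called (median 1.76, camera adjusted p = 0.047). Chosen after their values were seen, the leukocyte markers that rose were *CD14* (2.26 ± 0.47), *CD68* (1.77 ± 0.17) and *LCP1* (2.19 ± 0.39), and *LYZ*, encoding lysozyme, fell (-0.95 ± 0.26). *CD68* shares 82% and *LYZ* 34% of their exons with other annotated genes, so both are uncertain.

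In all, 5211 genes differed between 200 µM and control, 2760 higher and 2451 lower, of which 1303 had a log2 fold change of at least 1 in size. Without 200 µM replicate 3 the number was 7614, 3947 higher and 3667 lower. A fit of the 2 groups alone called fewer genes, 3875, with 2128 higher and 1747 lower. The near-equal totals of 5181 at 100 µM and 5211 at 200 µM therefore hold for the shared spread only. Pairs of 200 µM libraries had a chi-square per degree of freedom of 24.1 to 155, against 7.47 to 17.9 in the other groups. A spread shared by all groups can thus be too small for 200 µM. Fold changes at 200 µM rose with GC content (Spearman 0.22 across genes), and without 200 µM replicate 3, which had the opposite GC gap to the other libraries of its group, the value was 0.40, against 0.47 at 100 µM in the same fit.

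**Figure D3:**
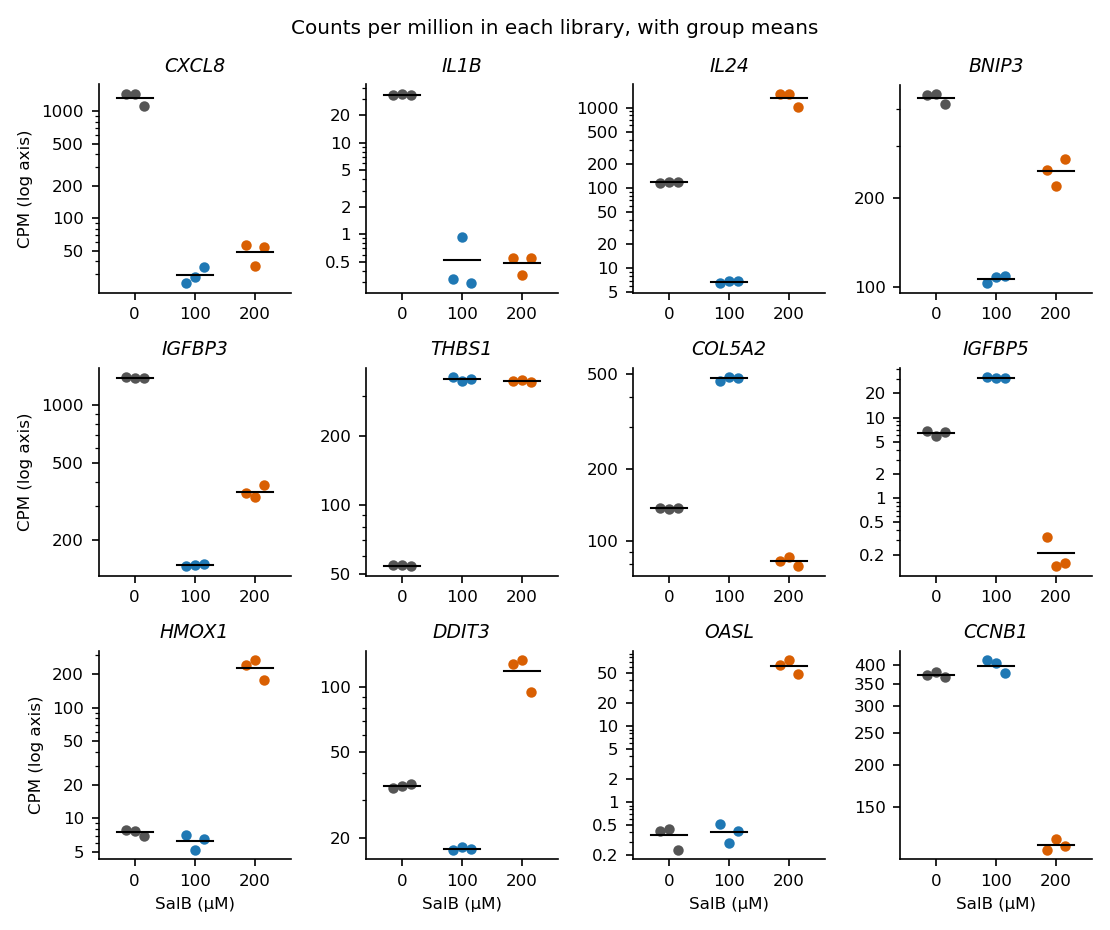
CPM on a log axis (y axis) of 12 named genes in the 3 libraries of each group (x axis), with points for libraries and bars for group means. *IL24* has a mean of 118 CPM in control, 6.77 at 100 µM and 1324 at 200 µM, and *THBS1* 54.4, 354 and 347.

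The comparison of 200 µM with 100 µM tested the difference between the doses itself. Inflammatory genes were higher at 200 µM, with 24 of 30 members of the NF-kB list higher and 2 lower (median log2 fold change 1.51; camera adjusted p = 1.7e-22). *IL24* was 196-fold higher at 200 µM (7.61 ± 0.18, adjusted p = 4.7e-08), and *BIRC3* was 29.8-fold higher. Interferon-stimulated genes had 31 of 40 members higher and 0 lower (34 and 1 adjusted over the list alone; median 1.32; camera adjusted p = 7.0e-22), and the G2/M list had 36 of 40 members lower and 0 higher (median -1.13; camera adjusted p = 1.1e-23). The matrix list was lower at 200 µM, with 22 of 39 members lower and 5 higher (23 and 7 adjusted over the list alone; median -0.39; camera adjusted p = 1.4e-05), and *COL5A2* was 5.83-fold lower, whereas the collagen receptor subunit *ITGA2* rose by 2.61 ± 0.14.

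The chemokine genes *CXCL10* (8.33 ± 0.39) and *CXCL11* (7.74 ± 0.55), which are induced by interferon, had 4 counts each over the 100 µM libraries, so their fitted folds depend on the prior count. For *CCL5*, with 1214 counts at 200 µM and 2 at 100 µM, the ratio was 697 with a 95% counting interval from 192 to 5761. The strongest decreases were in *IGFBP5* (ENSG00000115461, protein-coding, chromosome 2, 216672105 to 216695525), 147-fold lower at 0.209 ± 0.102 against 31.4 ± 0.292 CPM, and *ATOH8* (-5.26 ± 0.13). *LRRC17* (-4.16 ± 0.33) and *C4orf19* (-4.00 ± 0.29) also fell, but share 12% and 15% of their exons with other genes. *HMOX1* was 36.6-fold higher and *OASL* rose by 7.22 ± 0.27 and *IFIT2* by 4.03 ± 0.12. In the NF-kB and apoptosis lists, *TRAF1* rose by 4.29 ± 0.12 and *BCL2A1* by 4.10 ± 0.25. In the cell-cycle lists, *CCNB1* fell by 1.79 ± 0.07 and *KIF2C*, a mitotic kinesin, by 1.56 ± 0.07, while *CCNE1* rose by 0.98 ± 0.09.

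A further 9 lists were called between the doses and held with an estimated correlation. NRF2 targets had 26 of 33 members higher and 1 lower (median 0.89; camera adjusted p = 6.3e-19), with *TXNRD1* at 2.14 ± 0.08. Hypoxia targets had 21 of 34 higher and 2 lower (median 0.64; 2.6e-08), with *NDRG1* at 2.22 ± 0.09 and the vasodilator peptide gene *ADM* at 1.64 ± 0.08. Cholesterol genes had 15 of 25 higher and 0 lower (16 and 0 adjusted over the list alone; median 0.72; 2.5e-09), with *INSIG1* at 2.37 ± 0.10 and *HMGCS1* at 2.38 ± 0.09. MAPK output had 20 of 28 higher and 2 lower (21 and 2 adjusted over the list alone; median 0.84; 6.8e-11), with *DUSP5* at 3.93 ± 0.17 and *DUSP1* at 2.20 ± 0.13. The unfolded protein response had 20 of 29 higher and 1 lower (21 and 1 adjusted over the list alone; median 0.42; 1.8e-06), with *MANF*, a secreted folding-stress protein gene, at 1.11 ± 0.10. Metal response genes had 9 of 12 higher and 1 lower (median 0.74, and 0.48 without 200 µM replicate 3; 2.6e-08), with *FTH1* at 2.81 ± 0.13. Ferroptosis regulators had 14 of 25 higher and 2 lower (15 and 2 adjusted over the list alone; median 0.50; 1.1e-06), with *PTGS2*, encoding cyclooxygenase-2, at 4.34 ± 0.19. AHR targets had 6 of 11 higher and 0 lower (7 and 1 adjusted over the list alone; median 0.60; 0.0018), with *TIPARP*, a mono-ADP-ribosyltransferase induced by AHR, at 1.52 ± 0.11 and the uncertain *SERPINB2* higher too. DNA replication genes had 29 of 44 lower and 2 higher (30 and 2 adjusted over the list alone; median -0.47; 1.3e-06), with *RRM2* at -0.87 ± 0.07. These 9 lists and the NF-kB, interferon, G2/M and matrix lists, 13 of 20 called, held with an estimated correlation.

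The other 7 lists were lost with an estimated correlation. Apoptosis regulators had 18 of 36 members higher and 2 lower (camera adjusted p = 9.4e-05; adjusted p = 0.13 with an estimated correlation). Cytosolic ribosomal proteins had 34 of 75 higher and 0 lower (35 and 0 adjusted over the list alone; 0.0012; adjusted p = 0.29 with an estimated correlation), and 50 higher and 1 lower without 200 µM replicate 3, with *RPS4X* at 0.57 ± 0.08 and *RPL30* at 0.55 ± 0.08, both with near copies and the latter with 22% antisense overlap. p53 targets had 14 of 32 higher and 4 lower (15 and 4 adjusted over the list alone; 0.0072; adjusted p = 0.15 with an estimated correlation), with *PMAIP1*, a pro-apoptotic BCL2 family gene, at 1.69 ± 0.13 and *GADD45A* at 1.58 ± 0.10. The dedifferentiated list had 20 of 39 higher and 10 lower (20 and 11 adjusted over the list alone; 0.0091; adjusted p = 0.095 with an estimated correlation), with *SERPINE2*, a secreted protease inhibitor gene, at 1.64 ± 0.06 and the matrix gene *TNC* at -1.74 ± 0.08. ATF4 targets had 20 of 35 higher and 4 lower (9.3e-06; adjusted p = 0.10 with an estimated correlation), with *DDIT3* at 2.74 ± 0.13 and the angiogenic factor *VEGFA* at 1.52 ± 0.08. Heat shock genes had 15 of 25 higher and 2 lower (17 and 2 adjusted over the list alone; 8.9e-04; adjusted p = 0.058 with an estimated correlation). Autophagy genes had 22 of 43 higher and 4 lower (24 and 4 adjusted over the list alone; 4.3e-05; adjusted p = 0.13 with an estimated correlation), with *SQSTM1* at 3.40 ± 0.16 and *WIPI1*, which overlaps *ARSG* over 24% of its exons, at 2.14 ± 0.13.

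Lists not called between the doses were YAP and TGF-beta targets (12 higher and 8 lower of 28, or 12 and 9 adjusted over the list alone, camera adjusted p = 0.093), melanocyte genes (8 and 2 of 24), fatty acid synthesis (8 and 3 of 16), histones (10 and 1 of 19, and called with a filter of 1 CPM in 3 libraries, adjusted p = 0.0082), ribosome biogenesis (6 and 8 of 40, 6 and 7 adjusted over the list alone, or 10 and 16 without 200 µM replicate 3) and the markers of leukocytes (3 and 2 of 7), epithelium (2 and 2 of 9) and fibroblasts or endothelium (2 and 6 of 10). Glycolysis had 8 of 22 members higher and 3 lower (0.078) and was called without 200 µM replicate 3 (0.0016), after GC correction (0.012) and after the GC and length correction (0.013). OXPHOS subunits had 3 of 49 higher and 16 lower (2 and 16 adjusted over the list alone; 0.075) and were called as lower without 200 µM replicate 2 (0.015) and after the GC and length correction (-0.24, 0.015). Of the 13 mitochondrially encoded mRNAs 1 was lower (0 adjusted over the list alone; 0.51), and without 200 µM replicate 3 11 were lower and the list was called as lower (2.5e-07). Of the landmark genes, *CDKN1A* rose by 1.77 ± 0.15, *CCND1* by 1.32 ± 0.10 and *MYC* by 0.67 ± 0.10, and *MKI67* fell by 1.23 ± 0.23, while *BAX*, *BCL2* and *MITF* were not called (adjusted p from 0.25 to 0.48). Fold changes between the doses fell with GC content across genes (Spearman -0.22, and -0.04 without 200 µM replicate 3). Between the doses 6196 genes differed, 3133 higher at 200 µM and 3063 lower, of which 1926 had a log2 fold change of at least 1 in size.

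The fold changes of the 2 doses against control were also set beside each other. Across genes, which are not independent replicates, Pearson's r was 0.29 and Spearman's rho 0.27, with a covariance of 0.179. In 20 simulations of unchanged groups that shared their controls, r averaged 0.493 and reached at most 0.578, since shared controls alone correlate the fold changes. The covariance averaged 0.0483 there, so that the difference of covariances was 0.131. Genes called at both doses were 1067 higher at both and 836 lower at both, against 522 and 446 for independent lists. The simulations held no effects, averaged 0.2 and 0.1 calls at the 2 doses and had 0 shared calls, so they set no level for lists with real effects. Another 689 genes were called in opposite directions, 302 higher at 100 µM and lower at 200 µM and 387 the reverse, against 463 and 502 for independent lists. With a minimum log2 fold change of 1 these opposite calls instead exceeded independent lists, at 35 and 58 against 26.6 and 23.2. The 111 genes higher at both doses and the 80 lower at both in that setting exceeded independent lists too. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess of same-direction calls may come from the shared controls. Without 200 µM replicate 3, the genes called in the same direction at both doses numbered 3770 (1969 higher and 1801 lower) and those in opposite directions 1233 (588 and 645). For independent lists in that fit the numbers were 1131 and 1007 in the same direction and 1051 and 1084 in opposite directions. Genes in opposite directions, chosen after their values were seen except for *IL24*, *ATOH8*, *IGFBP5* and *CXCL10*, included *SLC16A6* (-2.07 at 100 µM and 2.22 at 200 µM), a monocarboxylate transporter family gene, *TAC1* (-2.73 and 2.06), which encodes substance P, and *KLF5* (-1.44 and 1.65), a transcription factor. *IGFBP5* changed by 2.27 at 100 µM and -4.92 at 200 µM, and *ATOH8* by 2.45 and -2.81.

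**Figure D4:**
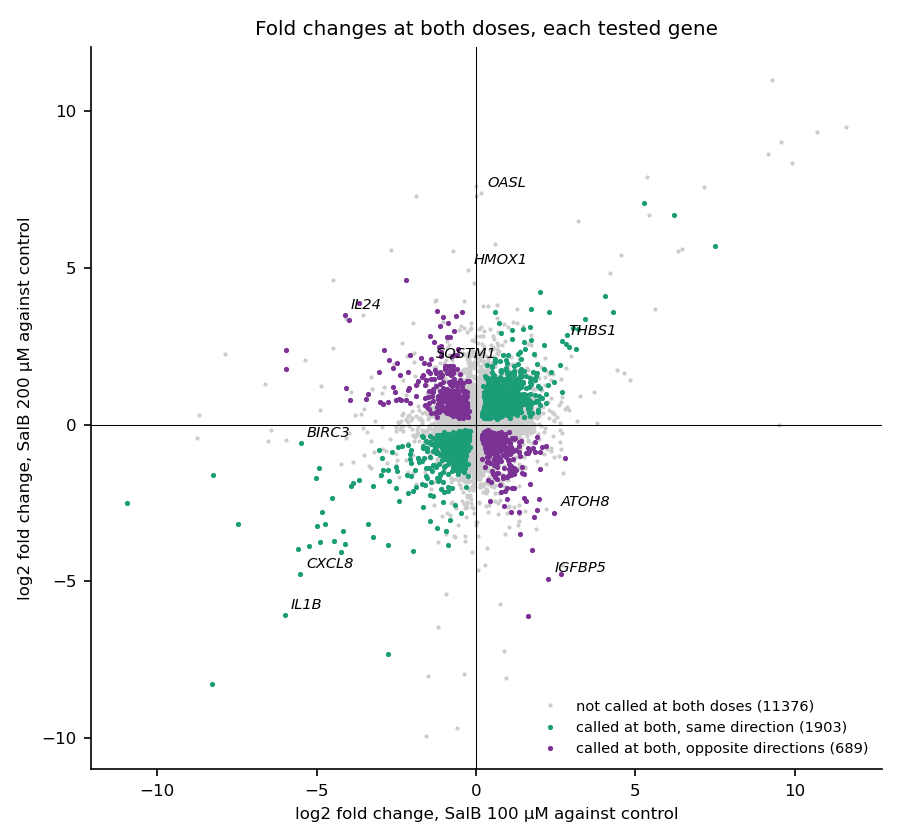
Log2 fold change against control at 100 µM (x axis) and 200 µM (y axis), with 1 point for each of 13968 genes and colours for genes called at both doses in the same or in opposite directions. Genes called in the same direction number 1067 higher and 836 lower, and 689 lie in the opposite quadrants; the fitted folds of genes with few counts depend on the prior count.

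The authors' deposited table of expression values named 100 features, 99 of them with a gene identifier, and all 99 were called in at least 1 of the 3 comparisons. Of these 99 genes in the authors' deposited table, 27 were higher and 53 lower at 100 µM, 47 higher and 41 lower at 200 µM, and 60 higher and 31 lower at 200 µM against 100 µM. Log2 fold changes from the counts and from the values in the authors' deposited table had a Pearson correlation of 0.999 across these genes in each comparison (pseudocount 0.01). The table was chosen on these samples, so its counts are not independent evidence.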

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

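The count of changed assembled transcripts was made after the files were examined, and the test of other splits of the libraries was fixed before the data were examined. The authors' count table also held 2142 transcripts assembled from the reads, which carry no Ensembl identifier and which the comparisons of genes did not use. Of 1518 assembled transcripts that passed the expression filter, edgeR called 221 between 100 µM and control at an adjusted p under 0.05, 113 higher and 108 lower. Between 200 µM and control it called 265, 117 higher and 148 lower. These 221 and 265 transcripts are listed because they differ from the control libraries in data outside the main measurement. In that measurement 5181 and 5211 of 13968 annotated genes were called. The files give no coordinates for them, so no gene or region is named.

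Each comparison of 3 libraries with 3 allows 10 splits, and 10 splits are too few for a share under 0.05. In fits of the 6 libraries compared, the real split called 8417 genes for 100 µM against control, and the highest of the other splits called 1. For 200 µM against control the real split called 3875 genes and the highest other 2. For 200 µM against 100 µM the real split called 4867 genes and the highest other 1. Each of the other splits mixed libraries of both groups, so the difference between the groups entered its spread. Few calls there would follow from any clear separation of the groups, so this contrast gives no level for chance and does not bear on the cause.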

How the results depend on the processing

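The GC and length corrections, the fit with assembled transcripts kept and the overlap without 200 µM replicate 3 were chosen after the data were seen. Of 148 results for named genes, 120 kept their direction and side of the threshold under every alternative run for them, 21 lost a call, 7 gained one and 0 reversed. All 21 lost their call with the minimum log2 fold change of 1, which removes smaller folds by construction. Only *RPS3A* and *MKI67* at 100 µM and *MITF* at 200 µM also lost it under another alternative. The fit without the 20 most abundant genes gave no value for *FTH1* or *SERPINE2*, so it covered 143 results that stayed the same and 1 that gained a call. With single libraries left out, 140 of the 148 kept direction and side of the threshold. Of 93 results for single lists, 49 kept direction and side of the threshold under every alternative run for them, fry included, and 80 with single libraries left out. Like camera, fry tests whether a list moves on balance, but against no change rather than against the other genes. It called 18, 23 and 29 lists in the 3 comparisons, against 12, 19 and 20 with camera, and 19 list results gained a call with it. A minimum log2 fold change of 1 lowered the counts by construction to 1103 (672 higher, 431 lower) for 100 µM against control, 1303 (751, 552) for 200 µM against control and 1926 (988, 938) for 200 µM against 100 µM. An adjusted p under 0.01 lowered them by construction to 2980 (1629, 1351), 3163 (1741, 1422) and 4014 (2072, 1942). The fit of the 2 groups alone called 8417 genes for 100 µM against control (4098 higher, 4319 lower). It called 3875 for 200 µM against control and 4867 for 200 µM against 100 µM. For 100 µM against control it compared the same libraries, and the median shift in log2 fold change was 0.0084. The 200 µM libraries then no longer entered the shared estimate of the spread. Pairs with 200 µM replicate 3 had a chi-square per degree of freedom of 114 and 155, against 7.47 to 24.1 in the other pairs. The parts of spread, filter and scaling were not separated. With estimated correlations 3 lists were called for 100 µM against control and 13 for 200 µM against 100 µM. That test raised p-values of lists that kept their call too. The camera adjusted p of the NF-kB list at 100 µM went from 1.1e-67 to 5.1e-05. A call lost there does not by itself show that the members of a list vary together. Genes called in the same direction at both doses numbered 191 with the minimum fold and 3770 without 200 µM replicate 3, and the cause of the latter was not tested.

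With single libraries left out, the counts ranged from 3469 to 7943 for 100 µM against control (1837 to 4056 higher, 1613 to 3887 lower), from 3719 to 7614 for 200 µM against control and from 4813 to 7668 for 200 µM against 100 µM. The highest value in each case came without 200 µM replicate 3. For 100 µM against control that library enters only through the shared estimate of the spread, the filter and the scaling, which were not separated. For the other comparisons the cause was not tested. Numbers of called lists ranged from 11 to 14, 18 to 19 and 20 to 22, and the correlation of the doses from 0.23 to 0.39. The list of mitochondrially encoded mRNAs at 200 µM reversed: its median of 0.22 became -0.51 without 200 µM replicate 3, with values from -0.51 to 0.48 over left-out libraries, and that library holds 4.75% of its counts in these mRNAs against 1.87% and 1.83% in the others. DESeq2, limma-voom, RLE scaling, both filters and the fit without the 20 most abundant genes left the numbers of called genes within 1.5 times. Scaling by total count moved the median of all genes by 0.06, -0.02 and -0.09 in the 3 comparisons, and gave 2946 higher and 2143 lower for 100 µM against control, 2656 and 2620 for 200 µM against control, and 2629 and 3629 for 200 µM against 100 µM, so the balance of higher and lower calls depends on the scaling.

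Replicate numbers are shared between groups, but same-numbered libraries did not deviate together (r from -0.16 to 0.03), and 0 of 9 libraries lay closest to its own number. With the replicate number as a block, 4264, 4369 and 5404 genes were called in the 3 comparisons, no call of a named gene was lost, and the leukocyte marker list at 200 µM passed the threshold (median 1.76, adjusted p = 0.047). On simulated data, 2% of genes changed by 0.5 on the log2 scale were recovered for 100 µM against control. For 200 µM against control the share was 24%, but these single runs do not show a difference between the doses. Those runs called 128 and 145 genes against 5181 and 5211 in the real comparisons, so the adjusted threshold was stricter in the simulations. The shares therefore do not measure how many small changes were missed in the real data. Of the 5181 genes called at 100 µM, 1103 had a log2 fold change of at least 1 in size, and the rest were smaller.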

Other observations

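The tests of gene families, of GC bias between libraries, of the 3 lists after GC correction and of single swapped libraries were chosen after the results were seen, as were the genes named here. At 200 µM, genes of the KLF family of zinc-finger transcription factors rose together, with 11 of 15 measured members higher and 0 lower (median log2 fold change 0.87; camera adjusted p = 3.8e-08 over 175 families defined by a shared symbol stem; adjusted p = 0.088 with an estimated correlation). After GC correction the camera adjusted p was 1.1e-07. *KLF2*, known as a flow-responsive factor of endothelium, rose by 3.78 ± 0.10 at 200 µM and was not called at 100 µM (0.23). *KLF4*, a regulator of differentiation, changed by -1.13 ± 0.15 at 100 µM and 3.15 ± 0.15 at 200 µM, *KLF5* by -1.44 ± 0.24 and 1.65 ± 0.24, and *KLF6* by -0.92 ± 0.08 and 0.90 ± 0.08. Tested directly between the doses, 9 of 15 members were higher at 200 µM and 1 was lower (camera adjusted p = 2.0e-06; adjusted p = 0.090 with an estimated correlation).

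Other families were lower at 200 µM than in control. Intraflagellar transport (IFT) genes, which build primary cilia, had 15 of 18 members lower and 0 higher (median -0.42; camera adjusted p = 0.0050; adjusted p = 0.38 with an estimated correlation), with *IFT88* at -1.07 ± 0.14 and *IFT22* at -0.82 ± 0.10. SRSF splicing factor genes had 10 of 11 members lower and 0 higher (median -0.58; camera adjusted p = 0.0021; adjusted p = 0.38 with an estimated correlation), with *SRSF6* at -1.24 ± 0.07, and that call ended after GC correction (0.059). Genes of the large mitochondrial ribosomal subunit (MRPL) had 21 of 49 members lower and 0 higher (median -0.29; camera adjusted p = 0.0050; adjusted p = 0.38 with an estimated correlation). Of the 175 families, 9 were called at 200 µM against control, and none of them held with an estimated correlation.

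Fold changes at 100 µM rose with the GC content of genes (Spearman 0.48). For 3 lists at 100 µM, the medians after GC correction argue against a GC trend as the whole cause: -2.91 for the NF-kB list, -0.58 for hypoxia targets and 0.56 for the matrix list, each still called. The dedifferentiated (0.20 before and 0.07 after), YAP (0.55 and 0.36) and metal response (-0.26 and -0.12) lists lost their calls after the same correction. For the trend itself, the GC gap between libraries varied within the 200 µM group by 1.27 (log2), more than the 0.781 between the 100 µM and control means, but by 0.489 at most in any group without 200 µM replicate 3. Because that range rests on 1 library, GC bias in library preparation and an effect of the dose on GC-rich transcripts cannot be told apart.

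The library of 200 µM replicate 3 stood apart, at 1.39 times the distance that separated replicates 1 and 2, and its 13 mitochondrially encoded mRNAs were higher by 1.29 to 2.06 (log2) than the mean of the other replicates. After GC correction the ratio was 1.28 (1.27 and 1.29 to the single replicates), above the bound set beforehand for GC bias as the whole cause, by a narrow margin and with a spread chosen after the values were seen. GC bias may still account for part of the distance, since the ratio fell with the correction. Without the mitochondrially encoded mRNAs the ratio was 1.40, but so few genes could hardly move a distance over all genes, so that value leaves their part open. The mitochondrial share, RNA quality, handling and a real difference between cultures stay open, and no biological explanation was tested.

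Of 689 genes called in opposite directions at the doses, 302 were higher at 100 µM and 387 higher at 200 µM, against 463 and 502 for independent lists. With a minimum log2 fold change of 1 the relation was the reverse, with 35 and 58 against 26.6 and 23.2. After GC correction 565 of the 689 (82.0%) were still called in opposite directions, and without 200 µM replicate 3, 674 (97.8%) were. For these genes the tables argue against GC bias and against 1 aberrant library as the whole cause. The totals of 1041 and 1233 opposite calls add no support, since those fits called more genes. Both lay below independent lists. After GC correction they were 453 and 588 against 613 and 641. Without 200 µM replicate 3 they were 588 and 645 against 1051 and 1084. Each of the 9 libraries lay closest to another of its own group, so single libraries swapped between groups are argued against too, while an exchange of the labels of whole groups would not show in this test and stays open. A response that changes direction between 100 µM and 200 µM is a hypothesis that remains, with *IL24*, *CXCL10*, *IGFBP5* and *ATOH8* as genes to follow. Whether it comes from toxicity at the higher dose, from timing within 48 h or from separate targets was not tested.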
